A study of Mus musculus with 6 samples.

How the data were processed

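Bulk RNA sequencing libraries of primary splenic CD8+ T cells of wild-type mice were compared between a control lentiviral vector and a Flag-TRNP1 lentiviral vector, with 3 libraries per group. Per the labels' protocols, the cells were infected at a multiplicity of infection of 20 with 1 μg/ml each of antibodies against CD3 and CD28, 100 ng/ml interleukin 2 and 10 μg/ml of the transduction enhancer Vectofusin-1, and were cultured for 2 days. Total RNA was extracted with TRIzol, and libraries were made with a whole RNA or an mRNA kit, per the labels' protocols; which kit served which library is not given in the sources used here. The choice matters for transcripts without a poly(A) tail.

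The authors deposited a single table of normalized counts, a signal per gene and library. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, the annotation and the use of strand are not given in the sources used here, so genes that overlap or share reads with near-identical copies are uncertain. Each value in the deposited table is a whole multiple of the smallest positive value of its column: 100% of the values came out whole within a tolerance of 1e-06, and the reads recovered in this way summed to 18194337 to 31363666 per library. The steps of the deposited normalized counts equal the inverse of median-of-ratios size factors computed on these reads (largest difference 4.3e-15). The table had 19582 rows, 148 of them with transcript identifiers instead of gene identifiers; 146 of these were matched to a gene of GENCODE release M21 and added to it, which gave 19463 genes, of which 19438 were in that annotation. Names and coordinates are from GENCODE M21 on mm10 (GRCm38).

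The table holds normalized values, so the main test was limma on log2(normalized count + 1), with a mean-variance trend, for the 12526 genes with a normalized count of 10 or more in at least 3 libraries. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. A fold change on this scale understates the change of genes with low counts. Gene lists (40, written before the data were examined) were tested with camera at its preset correlation of 0.01, adjusted over the 35 lists with at least 5 tested genes, and again with an estimated correlation and with fry; no list kept its call with the estimated correlation. The reads recovered from the deposited values also allowed edgeR's quasi-likelihood test and DESeq2 as alternatives.

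Genes were named by a rule set before the data were examined: Trnp1; the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of 50 or more and no overlap between the groups, leaving out unnamed gene models, pseudogenes and immune receptor segments; up to 4 passing members of each list by adjusted p, or its 2 most abundant members where none passed; and a fixed panel of T cell, metabolic and chromatin genes. Other members that passed are named where a count needed them. Results of a few genes that this rule or a later test selected are not reported here.

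The replicate numbers are shared by both groups, but no label says that a number marks a shared mouse or day. Other pseudocounts, filters, scalings, variance models, count tests, a replicate block and leaving out each library in turn were chosen before the data were examined. Rows kept as deposited, a correction for GC content and transcript length by natural splines, and the same with a replicate block were added afterwards. Within groups, all pairs of libraries differed by more than counting noise (chi-square per degree of freedom 5.16 to 30.4), so no library was counted as a copy of another.

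The procedure was tested on 1 set of simulated counts with the means, dispersions and sizes of these libraries, in which 200 genes had known changes and 12375 genes passed the filter. Limma recovered 68.2% of the genes changed 1.5-fold, 75.8% of those changed 2-fold and 93.7% of those changed 4-fold, with 2.53% of its calls false. A list raised 1.2-fold in the same simulation was called. Genes were simulated without correlation, so the simulation does not test how often camera calls a list falsely. Each gene had the same dispersion in all libraries. The rates therefore do not cover a library that stands apart, as Flag-TRNP1 replicate 2 did in the data. Depth limits counting error only. The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.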

Results

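Gene expression was measured by bulk RNA sequencing in primary CD8+ T cells from mouse spleen that had been infected with a lentiviral vector, either a control vector (3 libraries) or a vector carrying Flag-tagged TRNP1 (3 libraries). Trnp1 encodes a nuclear protein studied mainly in neural progenitors of the developing cortex. The cells were infected in the presence of antibodies against CD3 and CD28 and of interleukin 2, and were cultured for 2 days. All 6 libraries therefore describe activated, dividing T cells. The libraries held 18194337 to 31363666 reads assigned to genes. The labels number the replicates 1 to 3 in each group but do not say whether they came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical. Values below are normalized counts, given as mean ± SD over 3 libraries, and log2 fold changes on the log2(normalized count + 1) scale with their SE, for Flag-TRNP1 over control vector.

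Trnp1 itself (ENSMUSG00000056596, chromosome 4, 133491100 to 133498550, mm10) was nearly silent with the control vector and clearly present with the Flag-TRNP1 vector, as the labels state. The control libraries held 0, 3 and 4 Trnp1 reads, and the Flag-TRNP1 libraries 53, 141 and 173. In normalized counts these were 0, 2.83 and 2.85 against 62.0, 172 and 172, a log2 fold change of 5.66 ± 0.60 (limma, adjusted p = 0.00557). Replicate 1 of Flag-TRNP1 carried the lowest amount of the 3. These counts do not tell transcripts of the vector from those of the chromosomal gene, and the share of cells that carried the vector was not measured. An exact permutation test of 3 against 3 cannot give a p below 0.1 for a single gene. Limma without the mean-variance trend gave the same fold change an adjusted p of 0.0913.

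The comparison asks how TRNP1 changes the expression program of activated splenic CD8+ T cells; the title of the series places it in work on metabolic and epigenetic reprogramming of these cells and on liver fibrosis. With Flag-TRNP1, 10 of 50 tested interferon-induced genes and 11 of 27 cytokine genes rose, 8 of 22 hypoxia response genes fell, and Ctla4 and Prdm1 fell. Camera called these 3 lists with its preset correlation between genes and not otherwise (adjusted p = 0.247 with an estimated correlation for each). Granzyme B, perforin, the cell cycle genes and the chromatin regulators that were listed in advance did not pass the test. Of 12526 genes tested, 176 changed: 114 rose and 62 fell (limma, adjusted p under 0.05). Of these, 24 changed at least 2-fold, 11 upward and 13 downward. The 3 libraries of each group did not overlap for any of the 176, as for 22% of all tested genes, where chance gives 10%.

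Besides Trnp1, the largest rises among genes with a mean count of 50 or more were in Enah, an actin regulator (1.43 ± 0.28), Xcl1, the chemokine lymphotactin (1.32 ± 0.18), Isg20, an interferon-induced exonuclease (1.29 ± 0.13), Rtp4, an interferon-induced chaperone (1.26 ± 0.20), and Csf2, which encodes the growth factor GM-CSF (219 ± 22.3 against 505 ± 53.6). Ly6c1, a surface marker of activated and memory CD8+ T cells (1.17 ± 0.16), Mx1, an antiviral GTPase (1.08 ± 0.16), Irf7, a transcription factor of the interferon response (1.01 ± 0.13), and Fgl2, a secreted immune regulator (0.99 ± 0.13), followed. Ly6c1 has a close paralog, Ly6c2, and how reads shared by both were counted is not stated, so its value is uncertain. The largest falls were in Selenbp1, a selenium-binding protein (-2.37 ± 0.27), Itga7, a laminin-binding integrin subunit (-1.68 ± 0.25), Acvrl1, a receptor of the TGF-beta superfamily (-1.43 ± 0.20), Smtnl2, a smoothelin-like protein (-1.42 ± 0.24), and P4ha2, a collagen prolyl hydroxylase (-1.38 ± 0.17). Slc35d3, of the nucleotide sugar transporter family (-1.35 ± 0.18), Sema4c, a semaphorin (-1.24 ± 0.25), Vldlr, a lipoprotein receptor (-1.17 ± 0.13), Pygl, a glycogen phosphorylase (-1.14 ± 0.22), and Sccpdh, a dehydrogenase-like protein (-1.06 ± 0.17), also fell. With each of the 6 libraries left out in turn, Pygl passed in 1 fit, Enah, Smtnl2 and Sema4c in 2, and Itga7, Rtp4 and Sccpdh in 3. Xcl1 lies on chromosome 1 at 164931644 to 164935527, and its normalized count was 688 ± 29.9 with the control vector and 1775 ± 595 with Flag-TRNP1. Selenbp1 lies on chromosome 3 at 94933056 to 94944758, and its count was 95.8 ± 19.1 against 17.9 ± 4.55.

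**Figure D1:**
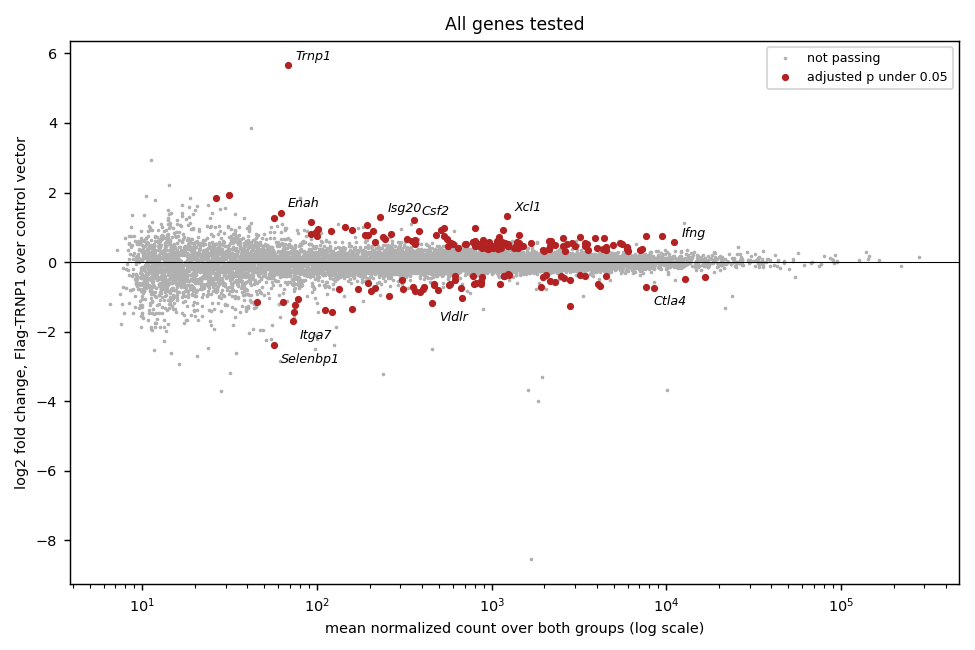
Log2 fold change of Flag-TRNP1 over control vector (vertical axis) against the mean normalized count over both groups (horizontal log axis) for the 12526 genes tested, with each of the 176 genes at an adjusted p under 0.05 as a larger red point. Trnp1 stands highest among them at 5.66 and Selenbp1 lowest at -2.37, and the grey points far below 0 did not pass the test.

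The number of called genes varied with the libraries included and with the variance model. It was 62, 42 and 154 without control vector replicates 1, 2 and 3. Without Flag-TRNP1 replicates 1, 2 and 3 it was 41, 336 and 100. A fit with a library left out also has less power, so a lower number alone does not show that the calls rest on that library. Limma without the trend called 0 genes (1750 at an unadjusted p under 0.05), edgeR 180 and DESeq2 392. The count of genes changed at least 2-fold was 11 without control vector replicate 2 and 52 without Flag-TRNP1 replicate 2.

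Of 50 tested members of the interferon response list, 10 rose, 0 fell and 40 did not pass over all genes. Adjusted over the list alone, 25 rose and 0 fell, and 49 of the 50 lay above 0. The risers were Isg20, Rtp4, Mx1, Irf7, Xaf1, Oas1b, Oas3, Ifi27, Gbp4 and Gbp6. Isg20 went from 132 ± 4.39 to 327 ± 50.8, Irf7 from 95.9 ± 3.84 to 194 ± 9.98, and Gbp4, a guanylate-binding GTPase, from 4414 ± 350 to 6406 ± 509. The list median was 0.33 and camera, limma's test of a list against all other genes, gave an adjusted p of 7.5e-18 with its preset correlation between genes. That call was lost with adjusted p = 0.247 with an estimated correlation, and fry, which asks whether a list moves one way, gave 0.025. The list of B cell markers, given below, was also shifted upward in the Flag-TRNP1 libraries (median 0.52). The sum of 6 markers with low counts, chosen after their values were seen, was 9.23 against 74.8.

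Cytokine genes were the list with the highest median, 0.57. Of 27 tested members, 11 rose, 0 fell and 16 did not pass. Adjusted over the list alone, 19 rose and 0 fell. Csf2, Xcl1, Lif, Osm, Ltb, Lta, Tnf, Ifng, Ccl3, Il13 and Flt3l rose. Besides Csf2, given above, Lif, a cytokine of the interleukin 6 family, went from 3363 ± 223 to 5436 ± 491, Ltb, which encodes lymphotoxin beta, from 2987 ± 158 to 4821 ± 513, and Ifng from 8895 ± 443 to 13292 ± 2141, though Ifng passed in 2 of 6 fits with a library left out. Camera gave an adjusted p of 7.5e-18 (adjusted p = 0.247 with an estimated correlation) and fry 0.025. The chemokine Ccl5 did not pass (-0.14 ± 0.17, adjusted p = 0.732). The B cell marker list moved in the same direction as this list.

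Among cytotoxic effector molecules, 3 of 20 tested genes rose, 0 fell and 17 did not pass. Adjusted over the list alone, 8 rose. The risers were the cytokines Tnf (0.72 ± 0.11) and Ifng (0.57 ± 0.10) and the protease Ctsw (0.49 ± 0.07). They were not the granzymes or perforin that give the list its name, and Tnf and Ifng were also counted in the cytokine list. With each library left out in turn, Tnf passed in 3, Ifng in 2 and Ctsw in 4 of 6 fits. Gzmb, the most abundant effector transcript named here, was at 160467 ± 10969 against 168455 ± 2692 (0.07 ± 0.11, adjusted p = 0.779), Prf1 had a log2 fold change of 0.16 ± 0.09 (adjusted p = 0.407) and Gzma one of 0.66 ± 0.14 (adjusted p = 0.0613). Gzma passed in 7 other settings, among them DESeq2 and the replicate block. The list shifted upward by camera (adjusted p = 1.2e-04), with adjusted p = 0.437 with an estimated correlation. The list of natural killer cell markers, given below, moved in the same direction (median 0.42, 8 of 9 above 0). Gzma belongs to both lists, so they are not independent.

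Of 15 tested profibrotic mediators, 3 rose, 0 fell and 12 did not pass. Of the risers, Osm and Il13 were already counted in the cytokine list. Adjusted over the list alone, 7 rose and 2 fell. Osm, a cytokine that acts on stromal cells, rose from 974 ± 16.9 to 1422 ± 37.6, Lgals3, which encodes galectin 3, from 849 ± 31.7 to 1286 ± 99.0, and Il13, a cytokine best known from type 2 immunity, from 68.5 ± 5.13 to 134 ± 24.7. Tgfb1, the central profibrotic cytokine, was at 4281 ± 188 against 4811 ± 100 (0.17 ± 0.06, adjusted p = 0.232). Camera called the list upward (adjusted p = 0.0128; adjusted p = 0.437 with an estimated correlation). Il13 passed in 1 of 6 fits with a library left out, and its adjusted p was 0.0506 with the GC and length correction.

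Of 22 tested members of the hypoxia response list, 8 fell, 0 rose and 14 did not pass. Adjusted over the list alone, 17 fell, and all 22 lay below 0. Besides Selenbp1 and P4ha2, those that fell were Ero1l, an oxidase of the endoplasmic reticulum (-0.76 ± 0.10), Mxi1, an antagonist of MYC (-0.75 ± 0.09), the mitophagy receptors Bnip3 (-0.58) and Bnip3l (-0.51), Ndrg1 (-0.54), and Egln3, an oxygen-dependent hydroxylase that marks HIF for degradation (-0.39). Ero1l went from 10643 ± 1432 to 6264 ± 450 and P4ha2 from 162 ± 27.8 to 61.1 ± 5.31. The list median was -0.38, with a camera adjusted p of 4.8e-16 (adjusted p = 0.247 with an estimated correlation) and 0.025 by fry.

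Of 22 tested glycolysis genes, 2 fell, 0 rose and 20 did not pass; adjusted over the list alone, 3 fell. Slc2a3, a glucose transporter, went from 5153 ± 634 to 3219 ± 300 and Aldoc, an aldolase, from 269 ± 31.0 to 161 ± 26.3, Aldoc passing in 1 of 6 fits with a library left out. The transporter Slc2a1 (0.05 ± 0.08), hexokinase Hk2 (-0.08 ± 0.08) and lactate dehydrogenase Ldha (-0.12 ± 0.11) did not pass. The list median was -0.08 (camera adjusted p = 0.0135; adjusted p = 0.464 with an estimated correlation), and the call was lost without control vector replicate 3 (adjusted p = 0.117).

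**Figure D2:**
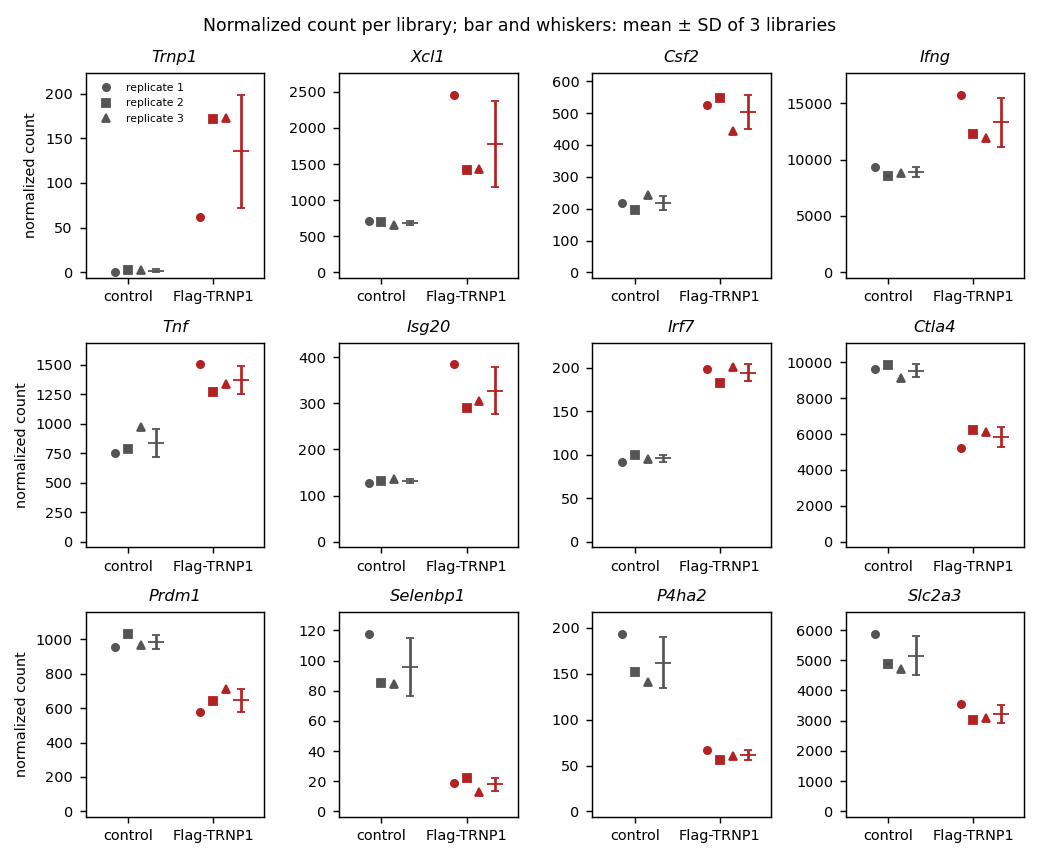
Normalized count (vertical axes from 0, one scale per gene) of 12 named genes in each of the 3 control vector libraries (grey) and the 3 Flag-TRNP1 libraries (red), with marker shapes for the replicate number and the mean ± SD beside the points. The groups do not overlap for any of these genes, and Flag-TRNP1 replicate 1 is lowest for Trnp1 (62.0) and highest for Xcl1, Ifng, Tnf and Isg20.

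Mitochondrial energy genes gave no firm direction. None of the 75 tested nuclear genes of oxidative phosphorylation passed, over all genes or adjusted over the list alone; Atp5b had a log2 fold change of 0.08 ± 0.08 and Atp5a1 one of 0.06 ± 0.08. Camera called that list lower (median -0.09, adjusted p = 0.0276, and 0.795 with an estimated correlation), but without Flag-TRNP1 replicate 2 the median was 0.018 with the test pointing upward (adjusted p = 0.374). The call was also lost with the replicate block (0.0664), without the trend (0.0874) and with the GC and length correction (0.334). Leaving out control vector replicate 2 (0.202) or 3 (0.133) lost it too. Of 15 mitochondrially encoded transcripts, 1 fell, the ribosomal RNA mt-Rnr1 (-0.64 ± 0.11, passing in 2 of 6 fits with a library left out), and 14 did not pass; adjusted over the list alone, 3 fell. That list was called lower (adjusted p = 0.0178, and 0.494 with an estimated correlation), and the test pointed upward after a GC and length correction (adjusted p = 0.414). The call was also lost without control vector replicate 1 (0.0569) and without Flag-TRNP1 replicate 1 (0.153). Mitochondrial transcripts have near-identical nuclear copies, so their values are uncertain. The tricarboxylic acid cycle (26 tested), fatty acid oxidation (28) and serine, one-carbon and amino acid metabolism (29) had 0 genes passing, adjusted over the list alone too, with Cs at 0.00 ± 0.07, Mdh2 at 0.11 ± 0.10, Acsl5 at 0.02 ± 0.07, Hadha at -0.04 ± 0.06, Cpt1a at 0.24 ± 0.08, Shmt2 at 0.14 ± 0.08 and Slc7a5 at 0.14 ± 0.10.

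In lipid synthesis, the desaturase gene Scd2 fell from 14974 ± 1200 to 10752 ± 493 (passing in 2 of 6 fits with a library left out), the single change among 18 tested genes of fatty acid synthesis, over all genes and adjusted over the list alone. In cholesterol biosynthesis, 1 of 24 tested genes rose, 0 fell and 23 did not pass; adjusted over the list alone, 4 rose and 1 fell. That list was called higher (median 0.12, adjusted p = 0.00179; adjusted p = 0.453 with an estimated correlation).

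Inhibitory receptors split. Of 23 tested genes of the list of inhibitory receptors and exhaustion factors, Ctla4 and Prdm1 fell, Cd160 rose and 20 did not pass; adjusted over the list alone, 7 rose and 3 fell, and the list was not called (adjusted p = 0.263). Ctla4, a coinhibitory receptor, went from 9526 ± 364 to 5852 ± 547, Prdm1, which encodes the effector differentiation factor BLIMP1, from 984 ± 42.8 to 645 ± 67.0, and Cd160 from 628 ± 9.21 to 938 ± 70.9. Pdcd1 (0.21 ± 0.09), Lag3 (-0.24 ± 0.08), Havcr2 (0.37 ± 0.12), Tigit (-0.12 ± 0.09) and Tox (-0.22 ± 0.11) did not pass. Among 31 lineage transcription factors, Prdm1 and Irf4 (-0.43 ± 0.07; Irf4 passed in 1 of 6 fits with a library left out) fell and 29 did not pass; adjusted over the list alone, 5 rose and 2 fell. Tbx21 (0.12 ± 0.07) and Eomes (0.24 ± 0.07) were among those not passing, and the list was not called (adjusted p = 0.151), except upward without Flag-TRNP1 replicate 3 (median 0.11, adjusted p = 0.0163).

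Of 29 tested genes of activation and costimulation, 7 rose, 1 fell and 21 did not pass; adjusted over the list alone, 10 rose and 3 fell. Tnfsf14 (0.76 ± 0.10), the early response factor Egr3 (0.68 ± 0.09), the early activation marker Cd69 (0.56 ± 0.08) and Tnfsf8 (0.55 ± 0.08) rose, as did Egr1, Nfkbid and Cish, whereas Irf4, a factor induced by receptor signalling, fell. Il2ra, the high-affinity interleukin 2 receptor chain, was at 36895 ± 470 against 34835 ± 2320 (-0.08 ± 0.08). The list was called higher (adjusted p = 0.0139; adjusted p = 0.453 with an estimated correlation). T cell receptor signalling was called higher as a list (median 0.09, adjusted p = 0.0178; adjusted p = 0.437 with an estimated correlation) with 0 of 30 genes passing over all genes; adjusted over the list alone, 8 rose and 3 fell. Cd8a (0.12 ± 0.06), Cd3e (-0.13 ± 0.06), Ptprc (0.07 ± 0.08) and Thy1 (0.43 ± 0.12) did not pass. Of 24 heat shock and immediate early genes, Egr1 (0.46 ± 0.09) and Zfp36 (0.39 ± 0.08) rose and 22 did not pass; adjusted over the list alone, 8 rose (list adjusted p = 0.0209; adjusted p = 0.494 with an estimated correlation). That list was no longer called without Flag-TRNP1 replicate 2 (adjusted p = 0.153) or with the GC and length correction (0.194, and 0.206 with the block). Egr1 passed in 2 and Zfp36 in 1 of 6 fits with a library left out, and Zfp36 did not pass with libraries rescaled to the same total (adjusted p = 0.0572), with the replicate block (0.0528) or with the GC and length correction (0.0600).

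None of 24 tested naive and memory factors passed, over all genes or adjusted over the list alone, with Satb1 at 0.06 ± 0.06, Tcf7 at 0.12 ± 0.07 and Il7r at -0.26 ± 0.08. Of 25 homing and adhesion receptors, Cxcr3, a chemokine receptor of effector T cells, rose from 352 ± 37.4 to 613 ± 101 (passing in 2 of 6 fits with a library left out) and 24 did not pass; adjusted over the list alone, 7 rose and 3 fell (list adjusted p = 0.551).

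**Figure D3:**
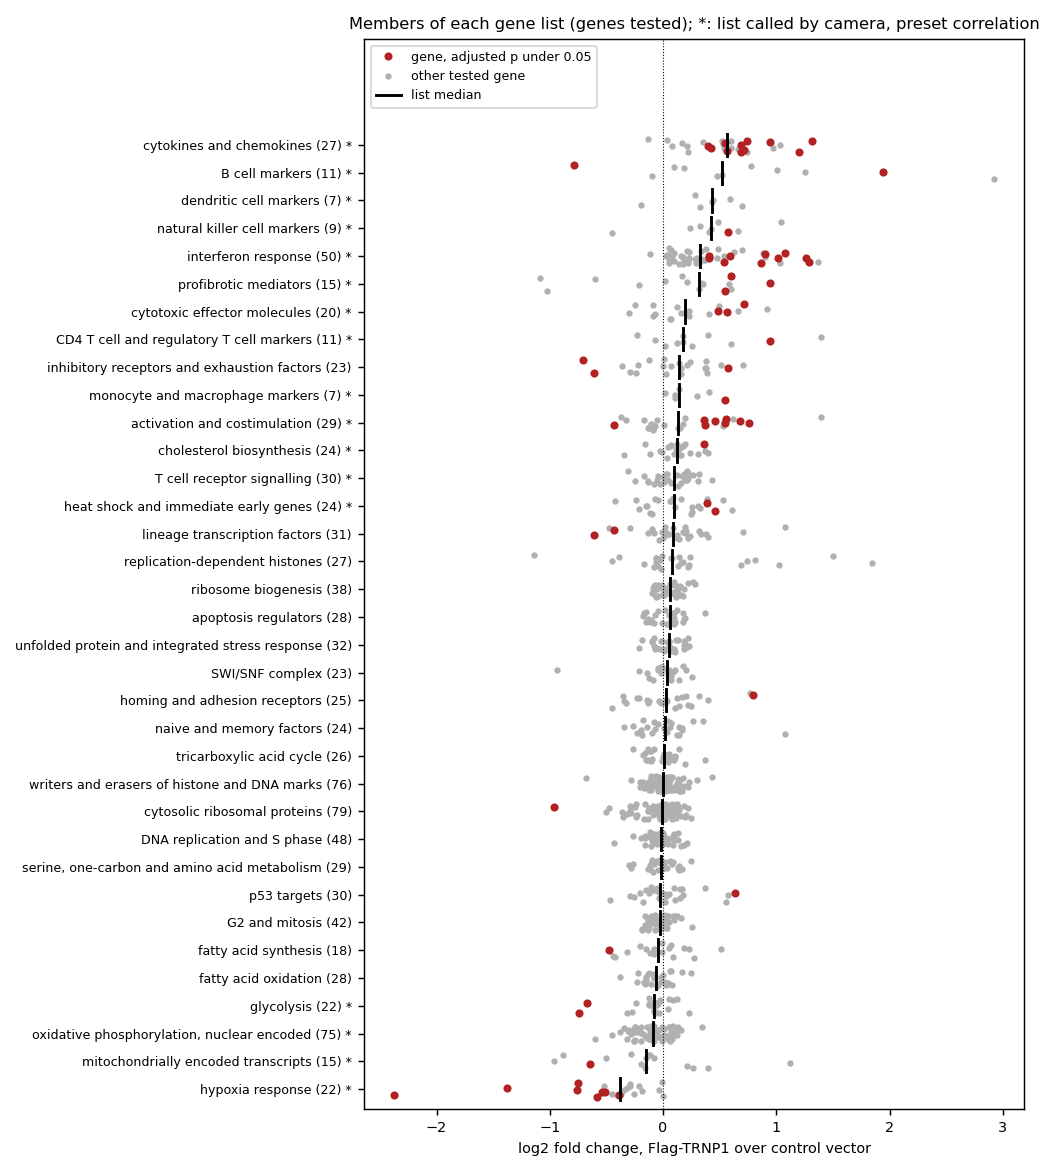
Log2 fold change of Flag-TRNP1 over control vector (horizontal axis) for every tested member of the 35 lists with at least 5 tested genes, ordered by their median (black bar), with genes at an adjusted p under 0.05 in red and the number of tested genes in brackets. The medians run from -0.38 for the hypoxia response to 0.57 for cytokines and chemokines, and an asterisk marks each of the 17 lists called by camera with its preset correlation.

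Chromatin and proliferation genes stayed close to 0. None of 76 writers and erasers of histone and DNA marks and none of 23 subunits of the SWI/SNF chromatin remodelling complex passed by limma, over all genes or adjusted over the list alone. Ezh2 had a log2 fold change of -0.15 ± 0.06, Dnmt1 of 0.06 ± 0.08, Uhrf1 of 0.19 ± 0.08, Arid1a of 0.18 ± 0.08 and Smarca4 of 0.07 ± 0.08. Likewise 0 of 48 genes of DNA replication and 0 of 42 of mitosis passed, with Mki67 at 17975 ± 605 against 16479 ± 1542, Top2a at -0.03 ± 0.07, Mcm5 at 0.22 ± 0.09 and Pcna at 0.03 ± 0.08. These 4 lists were not called (adjusted p = 0.872, 0.654, 0.565 and 0.191), but without Flag-TRNP1 replicate 2 the mitosis list was called lower (median -0.06, adjusted p = 0.0432).

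The remaining lists of cell state were not called in the same test. Unfolded protein and integrated stress response (32 tested), apoptosis regulators (28), ribosome biogenesis (38) and replication-dependent histones (27) had 0 genes passing, adjusted over the list alone too. Hsp90b1 was at -0.07 ± 0.07, Calr at 0.07 ± 0.07, Bcl2 at -0.08 ± 0.10, Ncl at 0.05 ± 0.14, Npm1 at -0.05 ± 0.10, Hist1h4i at -0.17 ± 0.19 and Hist1h3c at 0.13 ± 0.16. Of 30 p53 targets, the kinase gene Plk3 rose (0.64 ± 0.10) and 29 did not pass. Plk3 passed in 3 of 6 fits with a library left out. Adjusted over the list alone, 3 p53 targets rose and 3 fell. Of 79 cytosolic ribosomal proteins, Rps27 fell (-0.96 ± 0.18, passing in 2 of 6 fits with a library left out), also as the single change adjusted over the list alone, and its value is uncertain because ribosomal protein genes share reads with processed pseudogenes. Without Flag-TRNP1 replicate 2 the ribosomal protein list (median 0.10, adjusted p = 1.9e-04) and the histone list (0.27, adjusted p = 0.0106) were called upward. The ribosomal protein list was called lower without Flag-TRNP1 replicate 3 (-0.087, adjusted p = 5.9e-04) and without control vector replicate 1 (-0.03, adjusted p = 0.0469). Ribosome biogenesis (adjusted p = 0.0673) was called upward with no filter (0.0238), with the replicate block (0.0328) and without control vector replicates 2 or 3 or Flag-TRNP1 replicates 1 or 3. The median, the mean and the test differed in sign for naive and memory factors, the tricarboxylic acid cycle, writers and erasers, SWI/SNF and p53 targets, none of which was called.

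Among markers of other cell types, the 5 lists with enough tested genes were called higher with the preset correlation. The summed count of the B cell markers Ms4a1, Cd79a, Pax5, Cd22, Iglc2 and Bank1, chosen after their values were seen, was 9.23 ± 8.18 with the control vector and 74.8 ± 23.3 with Flag-TRNP1, from 3 to 87 reads per library, without overlap (exact permutation p = 0.1, the smallest possible). Of 11 tested B cell markers, H2-Aa rose from 11.7 ± 1.68 to 50.8 ± 24.1, H2-Ab1 fell from 218 ± 32.0 to 126 ± 14.3, although both encode chains of the same MHC class II molecule and passed in 1 and 2 of 6 fits with a library left out, and 9 did not pass; adjusted over the list alone, 4 rose and 1 fell (list adjusted p = 0.00633; adjusted p = 0.464 with an estimated correlation). Of 9 natural killer cell markers, Cd160 rose, which activated CD8+ T cells also express, and of 11 CD4 T cell markers, Il13 rose; adjusted over the list alone, 3 and 4 rose (list adjusted p = 0.00317 and 0.0139; adjusted p = 0.464 and 0.437 with an estimated correlation). Of 7 monocyte and macrophage markers, Hmox1, which many cells express, rose (0.55 ± 0.09), as it did adjusted over the list alone, and of 7 dendritic cell markers none passed, Bst2 (0.29 ± 0.11) and Cd83 (0.43 ± 0.15) included, while 4 rose adjusted over the list alone (list adjusted p = 0.0414 and 0.0178; adjusted p = 0.437 with an estimated correlation for both). The B cell list lost its call with a minimum mean count of 50 (adjusted p = 0.773), the CD4 T cell list without Flag-TRNP1 replicate 2 (0.112) and with the GC and length correction (0.0633), and the dendritic cell list without control vector replicate 3 (0.0693). The monocyte list kept its call in 2 of 6 fits with a library left out, and Hmox1 passed in 3 of them. The monocyte list lost its call with no filter (0.214) and with the replicate block (0.0664). Plasma cell, erythroid, stromal and other non-polyadenylated RNA lists had 3 tested genes each and the neutrophil list 0, too few for a list test. None of those genes passed over all genes, with Slamf7 at -0.01 ± 0.07, Tnfrsf13b at -0.12 ± 0.08, Gata1 at 0.81 ± 0.26, Car2 at 0.40 ± 0.30, Pecam1 at 0.07 ± 0.07, Epcam at 0.14 ± 0.21, Rn7sk at -0.47 ± 0.34 and Rn7s1 at -0.54 ± 0.46; adjusted over the list alone, 1 plasma cell gene fell and 1 erythroid gene rose.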

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

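The GC and length corrections and the table with rows as deposited were added after the data were examined; the other settings were planned. The 176 called genes kept their sign in every fit that tested them. The number called ranged from 41 to 336 when 1 library was left out, and was 392 with DESeq2, which called all 176, and 0 with limma without the trend; the cause was not tested. It was 170 to 232 with other pseudocounts, filters, scalings, robust variances or edgeR (180, sharing 174), 171 with rows as deposited and 215 with the GC and length correction (147 shared). The genes changed at least 2-fold numbered 11 to 52 with 1 library left out, 52 with DESeq2 and 0 without the trend, and with the GC and length correction 28, of which 17 were higher and 11 lower against 11 and 13. Trnp1 kept 5.66 without the trend at an adjusted p of 0.0913, and 5.01 to 6.14 with 1 library left out, past the threshold each time.

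Of 51 named genes that passed, 21 passed in all 6 fits that leave out a library, and each passed in at least 1. Xcl1 did not pass with robust variances (adjusted p = 0.0571). mt-Rnr1 and Il13 did not pass with the GC and length correction (0.164 and 0.0506).

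The replicate number as a block gave 253 genes, 170 of them among the 176, and 258 with the GC and length correction. Deviations of same-numbered libraries correlated at 0.12, 0.026 and 0.10 over genes, so the numbers do not establish pairs, although all 6 libraries correlated best with their own number, a hint from the data and not the design.

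Of the lists, 17 were called, and 14 to 20 with 1 library left out. The replicate block gave 16 and the GC and length correction 13. Fry called 3 (interferon, cytokines and hypoxia), and camera with an estimated correlation 0. That estimate widens the error of correlated lists, but this alone does not account for the lost calls. For the monocyte and macrophage list it was 0.0105, near the preset 0.01, yet camera's unadjusted p went from 0.0201 to 0.0810. The interferon, cytokine and hypoxia lists kept their call in all fits but the one with an estimated correlation. Lists that turned were oxidative phosphorylation without Flag-TRNP1 replicate 2 (median 0.018; -0.15 without replicate 3), cytosolic ribosomal proteins without it (0.10, and -0.087 without replicate 3), and mitochondrially encoded transcripts with the GC and length correction, with or without the block (0.10 in both); the cause was not tested.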

Other observations

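Chosen only after the results were seen were the gene families, the GC and length tests, all tests on Flag-TRNP1 replicate 2 and the tests of other cell types; the splits and leaving out each library were planned, but the limits for reading them were set once their values were known.

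Among guanylate-binding proteins, which attack intracellular pathogens, 5 of 10 tested genes rose and 0 fell, 2 of them (Gbp4 and Gbp6) already counted in the interferon list. Among PYHIN genes, a family with sensors of DNA, 3 of 10 rose. All 20 tested genes of MHC class I presentation had a log2 fold change above 0 (median 0.17), although only Tapbp (0.49), which encodes tapasin, passed. In the Ly6 family 2 of 6 rose, in the Schlafen family 1 of 7, and among cytokine receptors of the common gamma chain family Il2rg (0.37) and Il4ra (0.42) rose of 7. The families were picked from the called genes, so no test of them as groups is given. Many of these genes have close paralogs, so counts of single members are uncertain.

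Some called genes lie outside the lists. Cd274, which encodes PD-L1 (0.45), the inhibitory receptor gene Lilrb4a (0.94) and its close paralog Lilr4b (0.79) rose. Cd80, a ligand of CTLA4 (-0.63), Sh2d1a, the adaptor SAP (-0.76), Cd24a (-0.85) and Arrb1, an arrestin (-0.73), fell. Smad3, a mediator of TGF-beta signals, rose (0.47). These genes were named after their values were seen.

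Flag-TRNP1 replicate 2 lay at 50 on the first principal component (41.4% of the variance) and the other 5 libraries between -17.4 and -0.449. Fewer distinct RNA molecules would make its deviation shrink with abundance. Its variance beyond counting error was 3.10 times as large at means of 4096 or more as at 256 to 1024. Pseudogene rows raised this ratio. Over protein-coding nuclear genes, a form chosen after those rows were seen, it was 1.14, and 0.812 with a robust variance. A spread unrelated to abundance could hide such a fall, so the ratios speak only against fewer molecules as the sole cause. Flag-TRNP1 replicate 2 also had the fewest features above 0. It had 15996 at 18194337 reads, against 16588 at 18970852 reads in Flag-TRNP1 replicate 1. In Flag-TRNP1 replicate 2, 6 pseudogenes with a mean of 1000 or more elsewhere were at 0, against 0 or 1 in each other library. Over protein-coding nuclear genes the SD of the deviation of this library was still 1.39 times the next highest. That set keeps the genes that share reads with such copies. It therefore cannot decide whether reads were placed differently among near-identical copies. This explanation stays open for the library as a whole, and for the 6 pseudogenes it stays untested. For mt-Co3 and its nuclear copy Gm10925 the sum varied 1.61-fold between libraries and Gm10925 alone 11.3-fold, a value between the limits set for that test, so it stays open for this pair. Length and GC content explained 14.6% of its deviation and up to 22.9% in another library (21.7% and 42.3% over protein-coding nuclear genes), so such bias cannot be told apart from other causes, and no biological explanation was tested.

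As a hypothesis that no test here decides, the fall of 8 hypoxia response genes may reflect lower activity of the hypoxia-inducible factors in the Flag-TRNP1 cells. Bias by GC content and length is argued against as its whole cause, because the list median was -0.41 after the correction and -0.38 before. A single library is argued against, because the median nearest to 0 with 1 library left out was -0.32 and the farthest -0.43. Oxygen supply, cell density and the time of harvest of the cultures are not given by group and stay open beside an effect of TRNP1. Among glycolysis genes the fall was weak, with a list median of -0.08. There 20 of 22 genes did not pass, Slc2a1, Hk2 and Ldha among them, though 17 of the 22 lay below 0.

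As a hypothesis, the rise of interferon and cytokine genes may be a response of the T cells to TRNP1 or to the vector preparation, which the design confounds. Flag-TRNP1 replicate 1 had the lowest Trnp1 (62.0) but the highest Xcl1, Isg20, Ifng and Tnf. Its sum of the 6 picked B cell markers was also the highest (102 against 60.9 and 61.7). Csf2 and Mx1 were instead highest in replicate 2, and Irf7 and Rtp4 in replicate 3. GC content and length are argued against, because the smaller of the ratios of corrected to uncorrected list medians was 0.955. In sum, 34 markers of B, plasma, myeloid, dendritic and natural killer cells rose by 334 normalized counts. The 21 called genes of the lists rose by 21639, a ratio of 0.0154. Cd74, an abundant B cell transcript, rose by only 128 of the 334, so B cell transcripts are argued against as the source of the summed rise. Most of the other markers had low counts, so the ratio does not decide for the other cell types. No CD4 T cell marker was among the 34. The CD4 T cell list was called higher by camera (adjusted p = 0.0139 with the preset correlation), so CD4 T cells stay open as a source. For the 7 called genes with a control mean under 200, Irf7 and Rtp4 among them, the rise was 731 in sum and the same ratio 0.456, so other cells as their source stay open. How the CD8+ T cells were isolated is not given in the sources used here, and a few other cells that act on the T cells through secreted factors stay open.

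With 10 splits of the 6 libraries into 3 and 3, the share of splits with a result as large cannot fall below 0.1. In 1 of the 10 splits, the real one, as many genes were called (176, against at most 2 in another split), as many changed at least 2-fold (24 against 2), and as many lists were called (17 against 2 to 15 in the other 9 splits).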
